A study of Mus musculus with 6 samples.

How the data were processed

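The data were RNA sequencing counts of 6 mouse colon tumours, 3 from APC-WT cachectic mice and 3 from APC-KI recovered mice. Per the labels' protocols, tumours were pinched away from the muscle beneath, total RNA was purified with an on-column DNase step, and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks the strand. Per the submitters' processing notes, Trim Galore 0.6.4, cutadapt 2.5, STAR and DESeq2 1.37.6 were used, with the mouse builds GRCm38 and mm10 named. The roles of these tools, the counter, its strand setting and the annotation release were not given in the sources used here. The deposited table held raw whole-number counts per Ensembl gene for all 6 libraries, per the file headers and values, and whether reads or fragments were counted was not stated.

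The table had 53700 gene rows and no row of totals or unassigned reads. Symbols were taken from GENCODE release M21, which named 52093 identifiers and left 1607 under their identifier. Only 35 identifier versions equalled those of M21, so the counts were made on another release, and M21 served here for names, gene types and neighbourhood alone. For 67 symbols with more than 1 identifier, the identifier with the highest total took the symbol. No coordinates are given for this reason. Reads shared between near-identical copies may be split in ways that depend on the counter.

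Groups were taken from the sample titles. Genes were kept with edgeR's filterByExpr, scaled with TMM factors and tested with edgeR 4.0.16 (estimateDisp, robust glmQLFit, glmQLFTest) in R 4.3.3, group being the sole term. Fold changes are APC-KI over APC-WT, and p values were adjusted by Benjamini-Hochberg over the 19127 genes tested, with a threshold of 0.05. Values per library are CPM, the deposited counts scaled to library size with the TMM factors. Intervals on count ratios are exact 95% binomial intervals and cover counting error only, and a group with 0 counts was set to a floor of 3 counts over the group. Within groups, libraries differed far beyond sampling noise (chi-square per gene between 40.1 and 114.5), so each counted as a separate replicate.

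Before the data were examined, 31 gene lists with 529 genes were fixed for Wnt signalling, epithelial and other cell types, cachexia-associated factors, immunity, metabolism, RNA quality and sex. Of these 30 had at least 4 genes tested, and the sex-linked list had Xist alone, which did not pass (log2 change 1.53, adjusted p = 0.67). Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Genes were named by a rule fixed at the same time. It took Tcf7l2, Tcf7l1, Tcf7 and Lef1. It took the 12 largest increases and 12 largest decreases among genes past the threshold with an average log2 CPM of at least 1 and groups that did not overlap, without unnamed models, pseudogenes and antigen receptor segments. From each list it took up to 4 members with the smallest p, and from the cachexia list all members past the threshold. Some genes that the rule takes are not reported here. A list of mast cell genes and a list of pan-epithelial genes were added after the data were seen.

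The same steps were tested on simulated data for this comparison, with 18810 genes drawn from the means and sizes of the real libraries. In it 100 genes were changed 2-fold and 100 were changed 4-fold. Among those whose fitted change had the true direction, 49% and 91% were called. Of 148 calls 9 were unchanged genes (6.1%). A list of 20 genes raised 1.5-fold was called, and 0 of the unchanged lists were. Each gene was drawn independently of the others. The simulation therefore cannot show how the list test behaves when genes vary together, as in the cell cycle list (estimated correlation 0.798).

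Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals only, no filter and a stricter filter (CPM above 1 in at least 3 samples), the replicate number as a block, removal of mitochondrially encoded genes and the 10 most abundant genes, and each library left out in turn. After the Y-linked genes were seen, a fit over the 4 libraries without Y-linked counts and a fit with their presence as a covariate were added. The sex of the animals was not given in the labels. Library totals, the share of the 10 most abundant genes and the mitochondrial share were compared by exact two-sided permutation tests.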

Results

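Gene expression was measured by RNA sequencing of bulk colon tumours in 2 groups of 3, taken here as 1 tumour per mouse. The 3 APC-WT mice kept their endogenous Tcf7l2, had received doxycycline for 10 days and were cachectic, which means that they showed the wasting syndrome of advanced cancer. In the 3 APC-KI mice doxycycline represses Tcf7l2 throughout the body. They had received doxycycline for 6 weeks and had recovered. Both sets received 100 mg/kg doxycycline in the food, so genotype, time on doxycycline and cachexia state cannot be separated in this comparison. The libraries held 63921108, 54424511 and 51777342 counts in APC-WT replicates 1 to 3 and 55427560, 54895823 and 56825956 counts in APC-KI replicates 1 to 3. The comparison asks how tumours differ once Tcf7l2 is repressed and the animals have recovered from wasting.

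Tcf7l2 (ENSMUSG00000024985), which encodes a transcription factor that binds beta-catenin at Wnt target genes, was the gene repressed by design. It was 7.39-fold lower in APC-KI tumours, at 41.2 ± 4.84 CPM in APC-WT and 5.57 ± 1.23 CPM in APC-KI (SD, n = 3 each). The single libraries held 44.1, 43.8 and 35.6 CPM in APC-WT and 4.5, 6.9 and 5.3 CPM in APC-KI, so that 13.5% of the APC-WT level remained. The log2 change was −2.89 ± 0.19 (SE, edgeR adjusted p = 0.00124). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Of the related factors, Tcf7 fell by 1.17 on the log2 scale (SE 0.12, adjusted p = 0.00431) and Tcf7l1, which mostly acts as a repressor of Wnt targets, rose by 1.10 (SE 0.21, adjusted p = 0.0179). Lef1 had a log2 change of −0.78 ± 0.27 that did not pass (adjusted p = 0.0861).

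**Figure D1:**
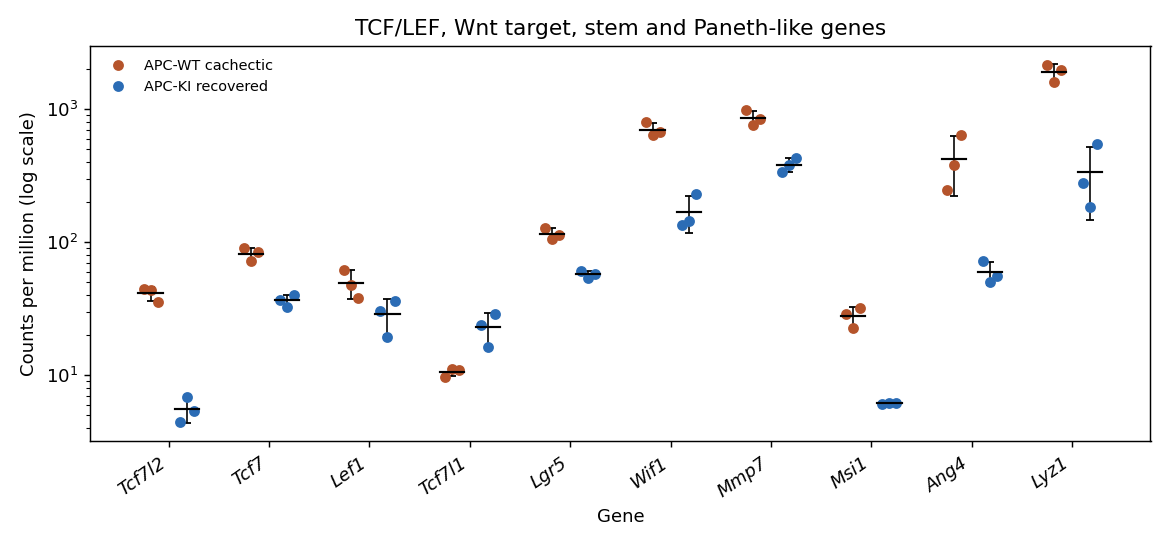
Expression in CPM (log axis) of 10 genes in each of the 6 libraries, with a dot per library, a horizontal bar at the group mean and error bars of 1 SD (n = 3). Tcf7l2 lay between 35.6 and 44.1 CPM in APC-WT tumours and between 4.5 and 6.9 CPM in APC-KI tumours, and of the genes shown Tcf7l1 alone was higher in APC-KI tumours.

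Across the transcriptome the 2 groups were far apart. Of 19127 genes tested, 3847 changed at an adjusted p under 0.05, with 2388 higher and 1459 lower in APC-KI tumours. Changes over 2-fold were seen for 1362 higher and 552 lower genes. The values of the 2 groups did not overlap for 44.5% of genes, where chance gives 10% for 3 against 3. The first principal component held 63.1% of the variance and separated the groups. The share of higher calls was 62.1% with TMM factors and 41% with library totals only, which gave 1978 higher and 2844 lower genes and moved the median log2 change of all genes by −0.116. Counts of Y-linked transcripts also differed between the sets of animals. The genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 19164 and 16055 counts in APC-WT replicates 1 and 2 and to 0 in the other 4 libraries. Xist, transcribed from the inactive X chromosome, stood at 0.33 and 0.56 CPM in those same APC-WT libraries, at 2221 CPM in APC-WT replicate 3 and between 2085 and 2194 CPM in APC-KI tumours. With the 4 libraries that lacked Y-linked counts alone, which leaves 1 APC-WT library that is assumed to vary like the APC-KI libraries, 178 genes were higher and 152 lower, and of the 3847 calls 277 passed again while 100% had the same sign. That sign was largely set in advance, because these 4 libraries were also in the fit that chose the genes. The numbers of calls also fell to 788 higher and 371 lower without APC-WT replicate 2 and to 973 and 300 without APC-KI replicate 1. They were 985 and 393 without APC-KI replicate 2, and 1567 and 891 without APC-WT replicate 1.

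Among the genes with the largest decreases were Mcpt1, Mcpt2 and Mcpt4, proteases of mast cell granules. Mcpt1 was 80.6-fold and Mcpt4 54.3-fold lower in APC-KI tumours, with some reads possibly shared among these related genes. The mast cell tryptases Tpsab1 and Tpsb2 were 81.9-fold and 40.1-fold lower, and carboxypeptidase Cpa3 and the IgE receptor chain Fcer1a 29.4-fold and 28.4-fold lower. Mcpt2 stood at 184 ± 131 CPM in APC-WT and 2.89 ± 1.61 CPM in APC-KI tumours, and Mcpt1 at 331.5 ± 235 CPM in APC-WT and 4.12 ± 2.49 CPM in APC-KI tumours (SD, n = 3 each, edgeR adjusted p = 0.0098). Mptx1, a secreted pentraxin of Paneth-like cells, had a log2 change of −8.00 ± 1.79 (adjusted p = 0.0282), with wide spread among APC-WT tumours (93.2 ± 121 CPM). The lipase-related gene Pnliprp2 fell from 219 ± 62.0 to 5.53 ± 2.85 CPM (adjusted p = 0.00354), and Gulo, the last enzyme of ascorbate synthesis, from 12.7 ± 4.25 to 0.31 ± 0.23 CPM (adjusted p = 0.0049). Gldn and the antisense transcript Tbx3os2 were 40.0-fold and 25.3-fold lower, the latter uncertain because the strand setting of the counting was not given in the sources used here. With limma-voom Mptx1, Mcpt2 and Gldn did not pass (adjusted p = 0.231, 0.0522 and 0.0522).

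The genes with the largest increases were rare in APC-WT tumours. Serpina1b, which encodes a copy of alpha-1-antitrypsin, rose from 0.174 ± 0.022 to 33.1 CPM, with 21.2, 21.8 and 56.2 CPM in the single APC-KI libraries (adjusted p = 0.00253), and its near-identical copies Serpina1c and Serpina1e rose with it. These copies share sequence, so the split of reads among them is uncertain. Serpina1c had 1 count in the 3 APC-WT libraries together, and its count ratio was 767, with a 95% interval of 137 to 30400 for counting error. Teddm3, Gvin1 and AC151990.1 rose to 9.75 ± 3.36, 9.97 ± 3.76 and 9.71 ± 8.64 CPM. Tfap2b, Ntrk2, BC049987, Chrdl2, Ntn5 and Vmn1r43 were up to 20.7-fold higher, and each had log2 changes of at least 3.59. Ntrk2 encodes a neurotrophin receptor and Chrdl2 a secreted BMP antagonist, and Ntrk2 did not pass with limma-voom (adjusted p = 0.0826). Of the 12 genes with the largest increases, 6 passed the threshold over the libraries without Y-linked counts, with 1 APC-WT library, as did 5 of the 12 with the largest decreases.

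Wnt target genes fell as a group, with a camera adjusted p of 1.98e-09, and adjusted p = 0.451 with an estimated correlation. Of 24 measured, 18 were lower and 0 higher, with 20 lower when adjusted over the list alone, and the median log2 change was −1.09. Lgr5, a receptor for R-spondins on stem cells, was 2.02-fold lower (116 ± 11.4 against 57.4 ± 3.37 CPM), the secreted Wnt inhibitor Wif1 4.14-fold and the protease Mmp7 2.25-fold lower. Intestinal stem cell markers, 6 of which are also in the Wnt target list, held 8 lower and 0 higher of 14, both over all genes and adjusted over the list alone, with a median of −0.71 (camera adjusted p = 0.000367, and adjusted p = 0.451 with an estimated correlation). All 6 shared genes were among those that fell, and of the unshared markers only Msi1 and Cdk6 fell. Msi1, an RNA-binding protein of crypt cells, was 4.54-fold lower, and the shared gene Tnfrsf19 and Cdk6 were 2.36-fold and 1.66-fold lower. The unshared Olfm4, Smoc2, Cdca7, Rgmb, Slc12a2 and Prom1 did not pass. Their log2 changes were −0.45, −0.17, −0.06, 0.0003, 0.01 and 0.61. Among TCF/LEF factors and Wnt pathway components, which share Tcf7 and Lef1 with the Wnt target list, 4 of 20 were lower and 3 higher (8 and 3 adjusted over the list alone), with no call for the list in camera (adjusted p = 0.064, and 0.482 with an estimated correlation), while fry passed it (adjusted p = 0.0327). The beta-catenin cofactor Bcl9 fell by 0.86 and the receptor Fzd5 rose by 1.29 on the log2 scale.

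Of 13 Paneth-like and deep crypt secretory markers measured, 8 fell and 0 rose, with 9 lower when adjusted over the list alone, and the median was −2.52, or −1.43 over the libraries without Y-linked counts. Of those that fell, Mmp7 is also in the Wnt target list and Kit is also a mast cell gene. The antimicrobial genes Ang4, Lyz1 and Pla2g2a were 7.15-fold, 5.71-fold and 3.54-fold lower, and Lyz1 stood at 1913 ± 274 CPM in APC-WT and 335 ± 188 CPM in APC-KI tumours. The list had a camera adjusted p of 0.000125, and adjusted p = 0.451 with an estimated correlation. Of 18 ribosome biogenesis and MYC-associated genes 9 fell and 0 rose (13 lower adjusted over the list alone), with a median of −0.27. Nop56, Npm1, Nop16 and Nolc1, which act in the nucleolus, were between 1.23-fold and 1.36-fold lower. The list had a camera adjusted p of 0.000432, and adjusted p = 0.451 with an estimated correlation. Of 24 cell cycle genes, 2 of the replication helicase, Mcm7 and Mcm2, were lower (1 adjusted over the list alone), with a median of −0.13. The median was −0.25 with library totals only. The cell cycle list passed at an adjusted p of 0.0387, had adjusted p = 0.653 with an estimated correlation and 0.328 in fry, and did not pass without APC-WT replicate 2, APC-WT replicate 3 or APC-KI replicate 3 (adjusted p = 0.077, 0.305 and 0.205), with a median of −0.026 without APC-WT replicate 3. Without APC-WT replicate 1 its median was −0.252 (adjusted p = 0.000173), and over the libraries without Y-linked counts −0.281 (adjusted p = 5.37e-05). Rrm2 and Mcm4 did not pass, at −0.42 and −0.36.

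The lists of absorptive, goblet and enteroendocrine markers passed as higher, with 20 of 58 members higher and 2 lower. They had camera adjusted p of 0.00233, 0.0093 and 0.00665, and adjusted p = 0.482, 0.479 and 0.451 with an estimated correlation. In fry the absorptive and goblet lists did not pass (adjusted p = 0.0522 each). Of 24 absorptive colonocyte markers, 11 rose and 2 fell (14 and 3 adjusted over the list alone), with a median log2 change of 1.12. Lypd8, which keeps flagellated bacteria from the epithelium, rose 3.96-fold to 6480 ± 682 CPM and Cdhr5, a brush border cadherin, 2.19-fold. The 2 that fell were the sodium-proton exchanger Slc9a3, by 0.82, and the peptide hormone gene Guca2b, by 1.24 on the log2 scale. Of 18 goblet cell markers 5 rose and 0 fell (8 higher adjusted over the list alone), with a median of 0.57, or 0.352 without APC-KI replicate 1. The mucus genes Muc2 and Tff3 were 2.11-fold and 2.90-fold higher, and Creb3l1 and Sytl2 1.82-fold and 1.40-fold. Of 16 enteroendocrine markers 4 rose and 0 fell (5 higher adjusted over the list alone), with a median of 0.88. The granule protein Chgb rose from 8.24 ± 3.38 to 40.3 ± 0.32 CPM, and Scg2, Scgn and Sst, the last 2 below 1 CPM, rose as well. The goblet list did not pass over the libraries without Y-linked counts (adjusted p = 0.0665) or with those counts as a covariate (adjusted p = 0.0536), and the enteroendocrine list did not pass with the stricter filter on low counts (adjusted p = 0.171). Among 13 tuft cell markers 3 rose, both over all genes and adjusted over the list alone, and 0 fell. Dclk1 and Alox5ap were 2.94-fold and 1.77-fold higher, and Sh2d6 did not pass at −0.84. The tuft list had a median of −0.18 and a mean of 0.04, with no call (camera adjusted p = 0.844, and 0.916 with an estimated correlation).

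The lists of smooth muscle, enteric neuron and glia, fibroblast, endothelial and adipocyte markers passed as higher. Their camera adjusted p values were 9.68e-07, 0.00159, 1.43e-05, 0.000569 and 0.0254 in this order, and each list had adjusted p = 0.451 with an estimated correlation. The fibroblast list did not pass in fry (adjusted p = 0.0522). The protocol states that tumours were pinched away from the muscle beneath them. Of 15 smooth muscle markers 13 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 change of 2.12. Myh11, the myosin of smooth muscle, rose from 50.2 ± 18.0 to 288 ± 68.9 CPM, and Synm, Pgm5 and Mylk were 4.36-fold, 5.91-fold and 2.12-fold higher. Of 14 enteric neuron and glia markers 5 rose and 0 fell (6 higher adjusted over the list alone), with a median of 1.40, or 0.916 over the libraries without Y-linked counts. Prph and Snap25 were 3.63-fold and 2.74-fold higher, and S100b rose from 0.024 ± 0.027 to 0.33 ± 0.12 CPM. Of 20 fibroblast and matrix genes 5 rose and 0 fell (12 higher adjusted over the list alone), with a median of 0.92. That median was 1.40 without APC-WT replicate 3 and 0.367 over the libraries without Y-linked counts. Dcn, Mmp2, Postn and Thy1 were between 1.78-fold and 3.23-fold higher. Of 14 endothelial markers 5 rose and 0 fell (9 higher adjusted over the list alone), with a median of 0.57. Tie1, Plvap, Vwf and Ptprb were between 1.52-fold and 1.61-fold higher. Of 6 adipocyte markers Cidec and Plin4 rose and 0 fell (2 higher adjusted over the list alone), with a median of 0.71, while Fabp4 and Lpl did not pass at 0.42 and 1.09. Over the libraries without Y-linked counts the endothelial and adipocyte lists did not pass (medians 0.279 and 0.532, adjusted p = 0.0588 and 0.0983), and with Y-linked counts as a covariate the adipocyte median was 0.32 (adjusted p = 0.148). The adipocyte list did not pass without APC-WT replicate 2 (adjusted p = 0.0514), nor the neuron and glia list with the stricter filter (median 0.225, adjusted p = 0.103).

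**Figure D2:**
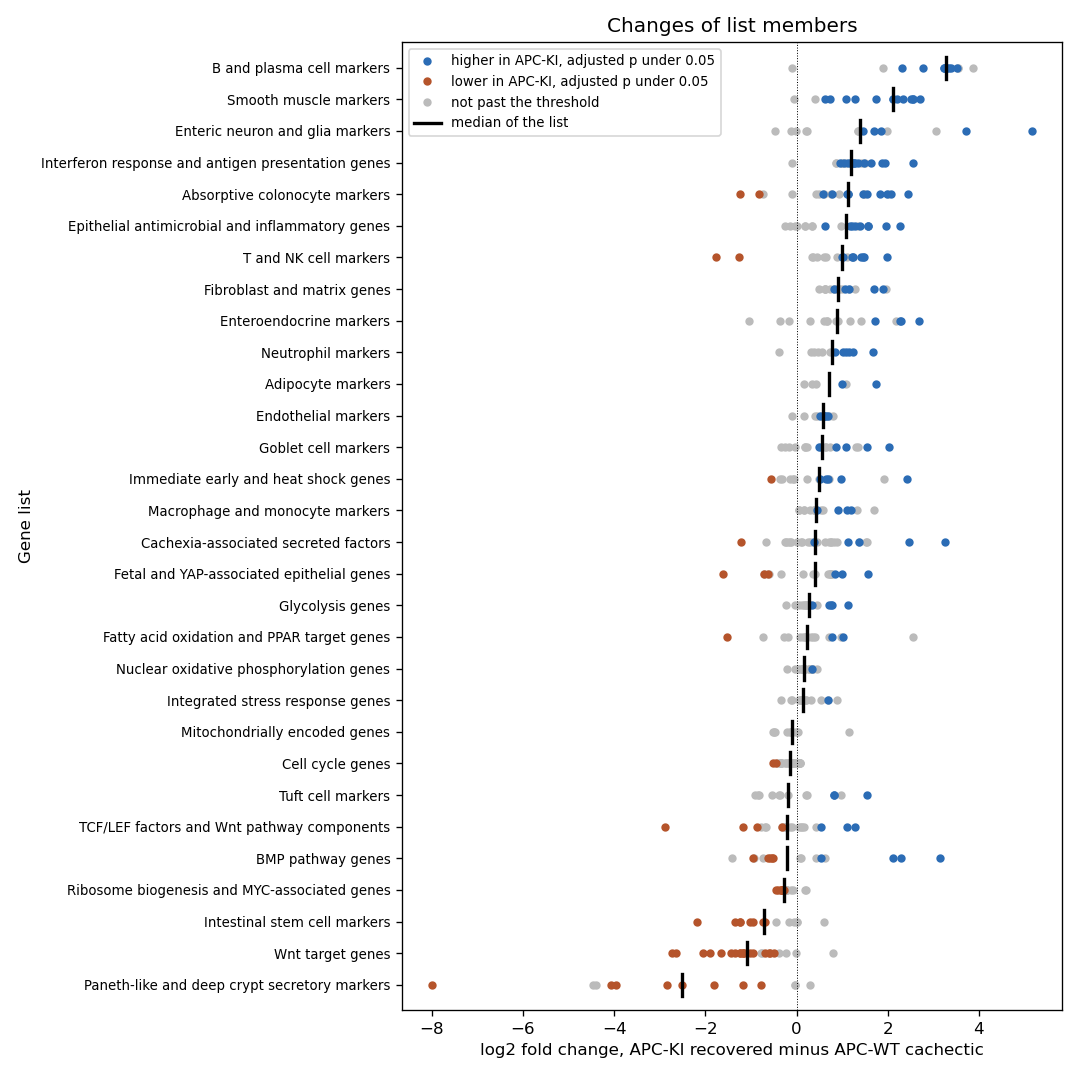
Log2 fold change (APC-KI minus APC-WT tumours) of each measured member of 30 gene lists, ordered by the list median, which is drawn as a vertical bar. Dots are single genes, coloured where the edgeR adjusted p was under 0.05, and the medians run from −2.52 for Paneth-like markers to 3.28 for B and plasma cell markers.

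Marker lists of B and plasma cells, T and NK cells, macrophages and neutrophils passed as higher. The camera adjusted p was 1.08e-05, 0.000569, 0.00243 and 0.0013 in this order, and each list had adjusted p = 0.451 with an estimated correlation. Of 15 B and plasma cell markers 9 rose and 0 fell (13 higher adjusted over the list alone), with a median log2 change of 3.28, which was 1.84 without APC-KI replicate 2. The heavy chain of IgA, Igha, rose from 580 ± 129 to 5448 ± 2578 CPM, the light chain Igkc from 342 ± 82.6 to 3462 ± 1223 CPM, and Jchain, which joins IgA into dimers, from 119 ± 34.1 to 1172 ± 476 CPM. Mzb1, a chaperone of antibody assembly, was 10.6-fold higher. Of 200 immunoglobulin and T cell receptor segments tested, 100 were higher. Of 18 T and NK cell markers 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 1.01. Foxp3, the factor of regulatory T cells, rose from 1.34 ± 0.29 to 5.33 ± 1.19 CPM, and Cd5, Cd2 and Trac were 2.34-fold, 2.67-fold and 2.03-fold higher. The 2 that fell, named after their values were seen, were the cytotoxic granule proteases Gzma (log2 change −1.77) and Gzmb (log2 change −1.26). Of 16 macrophage and monocyte markers 4 rose and 0 fell (5 higher adjusted over the list alone), with a median of 0.44, or 0.265 without APC-KI replicate 2. Cd14, Itgam and Fcgr1 were between 1.88-fold and 2.30-fold higher. Of 12 neutrophil markers 6 rose and 0 fell (8 higher adjusted over the list alone), with a median of 0.79. Ly6g, Stfa2l1, Cd177 and Cxcr2 were between 2.01-fold and 3.18-fold higher. The macrophage list did not pass over the libraries without Y-linked counts (adjusted p = 0.177).

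Of 24 interferon response and antigen presentation genes measured, 14 rose and 0 fell (23 higher adjusted over the list alone), with a median log2 change of 1.199. Gbp2, an interferon-induced GTPase, was 5.92-fold, Ifit2 3.81-fold, the immunoproteasome subunit Psmb8 2.29-fold and the factor Irf1 1.94-fold higher. Of 20 epithelial antimicrobial and inflammatory genes 9 rose and 0 fell, both over all genes and adjusted over the list alone, with a median of 1.08, or 0.595 without APC-KI replicate 2. Dmbt1, a secreted mucosal scavenger protein, rose from 1657 ± 101 to 8044 ± 869 CPM (adjusted p = 0.00119). Pigr, which carries IgA across the epithelium, was 2.42-fold higher, Slpi 3.90-fold and the acute phase gene Saa1 2.62-fold. The camera adjusted p was 2.17e-07 for the interferon list and 0.000229 for the antimicrobial list, and both had adjusted p = 0.451 with an estimated correlation.

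**Figure D3:**
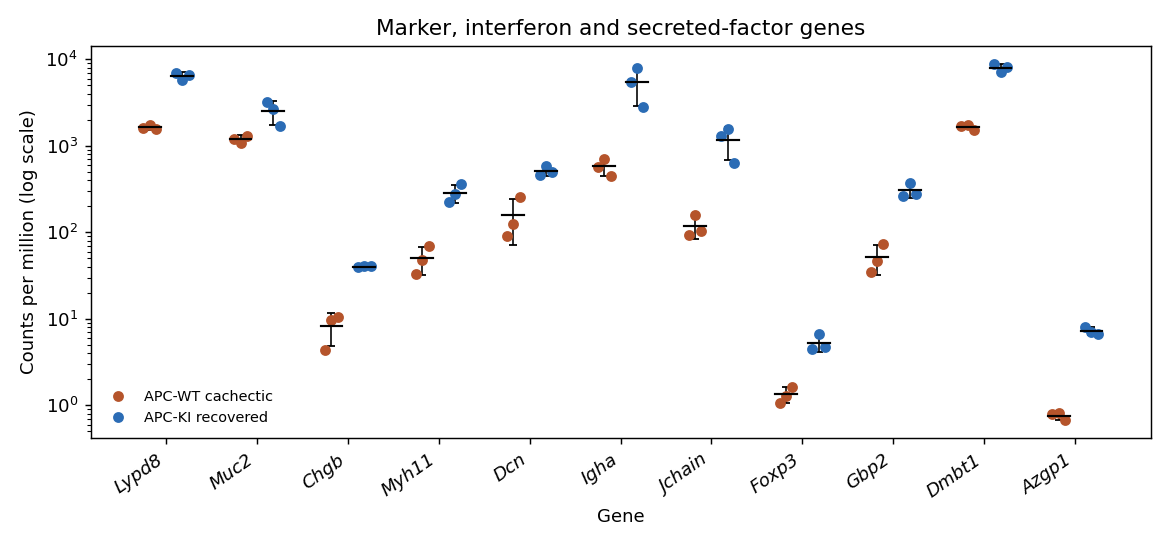
Expression in CPM (log axis) of 11 marker, interferon and secreted-factor genes in each of the 6 libraries, with a dot per library, a bar at the group mean and error bars of 1 SD (n = 3). In each gene shown every APC-KI library lay above every APC-WT library, with Igha at 580 ± 129 CPM in APC-WT and 5448 ± 2578 CPM in APC-KI tumours.

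Secreted factors that have been linked to cachexia mostly did not pass the test, and those that passed were mainly higher in tumours of the recovered animals. Of 28 measured, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a median log2 change of 0.41. Over all genes 3847 of 19127 passed, and 62.1% of those were higher, so these counts alone do not set the list apart. Azgp1, a lipid-mobilizing glycoprotein, rose 9.59-fold from 0.76 ± 0.07 to 7.30 ± 0.73 CPM (adjusted p = 0.00119). The cytokine genes Il1a, Ccl2 and Lif were 2.20-fold, 2.59-fold and 1.30-fold higher, and Ifng rose by 2.46 on the log2 scale from a level of 0.15 ± 0.04 CPM. Lif did not pass with library totals only (adjusted p = 0.113), nor Ifng with limma-voom (adjusted p = 0.081). Gdf11, a relative of myostatin, fell 2.33-fold from 102 ± 11.9 to 43.8 ± 14.8 CPM (adjusted p = 0.0225). Il6 and Gdf15, added here after their values were seen, did not pass, with log2 changes of 1.38 (adjusted p = 0.179) and −0.67 (adjusted p = 0.266). The list passed at a camera adjusted p of 0.00665, with adjusted p = 0.451 with an estimated correlation, and it did not pass over the libraries without Y-linked counts (median 0.19, adjusted p = 0.489), while without APC-WT replicate 3 its median was 0.634. Among BMP pathway genes 4 of 16 rose and 5 fell (4 and 6 adjusted over the list alone). The BMP antagonist Chrdl1 was 8.88-fold higher, and Id3, Smad7 and Bmp7 were between 1.49-fold and 1.95-fold lower. The BMP list had a median of −0.22 and a mean of 0.19, with no call (camera adjusted p = 0.599, and 0.719 with an estimated correlation). Of 17 fetal and YAP-associated epithelial genes 3 rose and 3 fell (8 and 4 adjusted over the list alone), with a median of 0.40 and no call in camera (adjusted p = 0.213, and 0.493 with an estimated correlation). Fry passed this list (adjusted p = 0.0495), and its median was 0.14 over the libraries without Y-linked counts. Anxa3 and Ly6a were 1.79-fold and 1.99-fold higher, and Cldn4 and Ajuba 1.55-fold and 1.64-fold lower.

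The medians of the metabolic lists lay between −0.11 and 0.27. Of 17 glycolysis genes 5 rose and 0 fell (7 higher adjusted over the list alone), with a median log2 change of 0.27, or 0.152 with library totals only. The hexokinases Hk2 and Hk1 were 2.18-fold and 1.72-fold higher, and Pfkp and the glucose transporter Slc2a1 1.68-fold and 1.63-fold. The list had a camera adjusted p of 0.0021, and adjusted p = 0.451 with an estimated correlation. Of 20 nuclear oxidative phosphorylation genes Ndufb8 rose (0 adjusted over the list alone), with a median of 0.17, and Cox6c, Cox5a and Cox7a2 did not pass at 0.35, 0.37 and 0.33. The list passed at a camera adjusted p of 0.0169, had adjusted p = 0.527 with an estimated correlation and 0.123 in fry, and did not pass with library totals only (median 0.053, adjusted p = 0.0845), without APC-WT replicate 3 (0.116) or without APC-KI replicate 1 (0.0692). Of 19 fatty acid oxidation and PPAR target genes Acadl and Pparg rose and Pdk4 fell 2.87-fold, with the same counts when adjusted over the list alone (2 higher and 1 lower), and Cd36 did not pass at 0.97. That list had a median of 0.23, or 0.115 with library totals only, and a camera adjusted p of 0.04, had adjusted p = 0.482 with an estimated correlation, and did not pass over the libraries without Y-linked counts (0.101) or without APC-WT replicate 2 (0.0976), APC-WT replicate 3 (0.0528), APC-KI replicate 1 (0.119) or APC-KI replicate 2 (0.0528). None of 13 mitochondrially encoded genes passed (0 over the list alone), with a median of −0.11, and mt-Nd5, mt-Nd6, mt-Co3 and mt-Atp6 had log2 changes of −0.20, −0.49, −0.52 and −0.48 (camera adjusted p = 0.184, and 0.495 with an estimated correlation). Their median was −0.209 without APC-KI replicate 1, −0.024 without APC-KI replicate 2, −0.228 with library totals only and 0.008 over the libraries without Y-linked counts. Of 15 integrated stress response genes Cebpb rose (0 adjusted over the list alone), with a median of 0.15, while Slc7a11, Ddit4 and Chac1 did not pass at 0.54, −0.35 and 0.89. The stress list had a camera adjusted p of 0.184, and 0.527 with an estimated correlation. Its median was 0.268 without APC-WT replicate 3, 0.086 without APC-WT replicate 2, 0.096 without APC-KI replicate 2, 0.034 with library totals only and 0.012 over the libraries without Y-linked counts. Of 15 immediate early and heat shock genes 5 rose and 1 fell, both over all genes and adjusted over the list alone, with a median of 0.50, or 0.119 without APC-KI replicate 3, and no call (camera adjusted p = 0.257, and 0.493 with an estimated correlation). Fos, Zfp36 and Hspa1b were 1.98-fold, 1.43-fold and 5.36-fold higher and Ier3 was 1.47-fold lower. Of the 30 lists tested, 23 passed with the preset correlation, 18 as higher and 5 as lower, and 0 passed with an estimated correlation. Fry, which asks whether the genes of a list move on balance 1 way, passed 20. These include the TCF/LEF and the fetal lists, which camera did not pass. Of the lists that camera passed, fry did not pass the cell cycle (adjusted p = 0.328), absorptive, goblet, fibroblast (0.0522 each) and oxidative phosphorylation (0.123) lists.

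The libraries differed little in depth and more in composition. Their totals did not separate the groups (exact two-sided permutation p = 1, n = 3 each). The 10 most abundant genes, led by mt-Co1 in every library, took 4.31 ± 0.30% of counts in APC-WT and 5.23 ± 0.25% in APC-KI (exact permutation p = 0.1). Mitochondrially encoded genes took 2.63 ± 0.27% and 2.30 ± 0.12% (exact permutation p = 0.1). Both p values are the smallest that 3 against 3 allows.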

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

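The fits over libraries without Y-linked counts and with Y-linked counts as a covariate were chosen after the data were seen. Tcf7l2 kept its direction and passed the threshold in every fit, with log2 changes between −3.07 and −2.68. The main count was 2388 higher and 1459 lower genes, and those of these genes that a fit tested kept their sign in every fit. Every fit shares libraries with the main fit that chose the genes, so the kept sign was largely set in advance. DESeq2 called more genes in both directions, 3362 higher and 2230 lower, over 21997 genes tested. Library totals only gave 1978 higher and 2844 lower, for which the scaling itself shifts all genes down. With the replicate number as a block 1195 were higher and 465 lower. Same-numbered libraries deviated from their group means with correlations of 0.03, −0.07 and −0.18. These values gave no sign of a shared effect of the number, but so few pairs cannot exclude one. Leaving out 1 library gave between 788 and 2542 higher and between 300 and 1595 lower genes. The lowest higher count came without APC-WT replicate 2 and the lowest lower count without APC-KI replicate 1. Over the 4 libraries without Y-linked counts 178 were higher and 152 lower, and with the covariate 220 and 195. Both rest on 1 APC-WT library for the group difference, by their construction. Of 127 named genes past the threshold besides Tcf7l2, 64 stayed past it in the same direction under every planned setting that gave a value. DESeq2 lost 0 of them, limma-voom 6 (Ntrk2, Mptx1, Mcpt2, Gldn, Ifng and Hspa1b), library totals only 7 (Sytl2, Postn, Lif, Ndufb8 and Cebpb among them), the fit without a filter 10, the block 37, and the fit without Y-linked libraries 92. Leaving out APC-WT replicate 1, 2 or 3 lost 28, 51 and 11 of them, and leaving out APC-KI replicate 1, 2 or 3 lost 50, 47 and 15.

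With an estimated inter-gene correlation 0 of the 23 lists passed in camera, 2 of the 30 tested had an unadjusted p under 0.05, and fry passed 20. The tuft cell list, not called, had a median of −0.179 but camera's direction was up, and that direction turned to down with the block (median −0.192), over the libraries without Y-linked counts (−0.247), with the covariate (−0.245) and without APC-WT replicate 1 (−0.151), and leaving out 1 library gave medians between −0.173 and 0.436. The BMP list, also not called, turned up in camera's direction over the libraries without Y-linked counts (median 0.09). The TCF/LEF and Wnt component list passed without APC-WT replicate 3 (adjusted p = 0.0342) or APC-KI replicate 1 (0.0388), and the integrated stress response list without APC-WT replicate 3 (0.0399). Xist, not called, turned to −0.06 in both fits that account for Y-linked counts, as their construction implies. The difference in the share of the 10 most abundant genes, 0.915 percentage points, was 1.434 without mitochondrially encoded genes and 1.93 for the 50 most abundant. For the other changes the cause was not tested. Depth limits the fold of genes at or near 0 counts in 1 group, such as Serpina1c with 1 APC-WT count.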

Other observations

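The genes of this part, the mast cell and pan-epithelial lists and all tests below except the other splits of the libraries and the test of neighbouring genes were chosen after the values were seen. Mast cell genes were much lower in APC-KI tumours. Of 18 measured, 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median log2 change of −3.32. The list holds the genes whose values prompted it, so no test of the list as a whole is given. Over the libraries without Y-linked counts, with 1 APC-WT library, the median was −3.01. Beside the granule proteases, the IgE receptor chain Ms4a2 fell from 5.02 ± 2.76 to 0.275 ± 0.039 CPM and the transcription factor Gata2 from 12.1 ± 2.20 to 3.11 ± 0.725 CPM (SD, n = 3). The amine transporter gene Slc18a2 fell by 2.99 on the log2 scale. Hdc, which makes histamine and is also used by other cells, rose by 1.10 on the log2 scale. Il1rl1 and Hpgds, also used by other immune cells, did not pass at −0.36 and 0.31.

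A few further genes, picked for their size of change and not as a group, were lower in APC-KI tumours. The homeobox genes Msx1 and Dlx3 fell from 19.1 ± 3.93 to 1.03 ± 0.233 CPM and from 15.8 ± 6.31 to 1.91 ± 1.01 CPM, and the growth factor gene Fgf3 from 10.6 ± 2.30 to 0.516 ± 0.139 CPM. The keratin Krt90 fell from 81.6 ± 66.7 to 4.27 ± 1.26 CPM, the metallothionein Mt4 from 88.2 ± 57.1 to 7.78 ± 4.45 CPM, and the receptor Lgr6 from 41.7 ± 16.2 to 5.46 ± 2.37 CPM. Pnliprp1, a lipase-related gene like Pnliprp2, fell from 244 ± 12.9 to 14.7 ± 9.13 CPM (adjusted p = 0.00601). The log2 changes of Msx1, Fgf3 and Krt90 were −4.20, −4.35 and −4.26, and −4.38, −4.67 and −2.85 over the libraries without Y-linked counts. Those of Dlx3, Mt4, Lgr6 and Pnliprp1 were −3.05, −3.50, −2.93 and −4.05, and −2.28, −1.94, −3.12 and −4.01 over those libraries. The values without Y-linked counts rest on 1 APC-WT library.

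Of the 10 splits of the 6 libraries into 3 against 3, only the real one reached 3847 genes past the threshold, which is 1 of 10, and the highest other split called 0 by edgeR. At an unadjusted p under 0.05 the real split had 7234 genes and the other splits at most 1242. For gene lists the real split passed 23, again 1 of 10, and the highest other split passed 20. The preset correlation thus also passes many lists for groupings that mix the genotypes. Each such grouping still holds part of the group difference, so neither its list calls nor its gene calls measure false calls. With 10 splits no share under 0.05 can be reached.

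Wnt target genes were lower while part of the markers of several other cell types were higher. Of 13 pan-epithelial genes 6 rose and 0 fell (8 higher adjusted over the list alone), with a median log2 change of 0.32. The 95% bootstrap interval of 0.15 to 0.46 resampled the genes and not the libraries. That median was 0.20 with library totals only and 0.28 over the libraries without Y-linked counts. Camera gave p = 0.223 for the list with an estimated correlation. These genes thus showed no fall as a group. A lower share of epithelial cells in the APC-KI pieces is not excluded, because bulk counts do not separate the share of cells from expression per cell. Other cell types moved apart, with medians of 3.28 for B and plasma cells (1.84 without APC-KI replicate 2), 0.57 for endothelium and −3.32 for mast cells. More non-tumour gut wall in the APC-KI pieces may contribute to the smooth muscle, nerve and absorptive signals, and the 2 members of those lists that fell, Slc9a3 and Guca2b, do not exclude it, since no normal colon library was analysed here. Sex stays open, because the Wnt target median of −0.88 over the libraries without Y-linked counts rests on 1 APC-WT library, and so stay the repression of Tcf7l2, the time on doxycycline and the recovery, which this design does not separate.

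For the mast cell genes, a variant at a single locus that acts on its neighbouring genes alone is argued against, because the 14 genes that fell lie at 9 separate places of the genome, more than 2 Mb apart. A variant that lowers mast cell number or acts at a distance was not tested. Sex is only partly confounded with the group, since APC-WT replicate 3 lacked Y-linked counts as the APC-KI libraries did. Over these libraries the median was −3.01, but this rests on 1 APC-WT library, so sex stays open. Whether the APC-KI tumours held fewer mast cells stays open, and counting these cells in stained sections would decide it.

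There were 17 genes near 0 in 1 group (below 0.2 CPM in every library) and above 1 CPM in every library of the other, 11 of them near 0 in APC-WT tumours. Klk1b22 and Akr1c21 had 0 counts in APC-WT tumours and were at least 128-fold and 130-fold higher in APC-KI tumours, against a floor of 3 counts over the group. For the Serpina1 copies, a shift of reads between near-identical genes is argued against, because the lowest APC-KI library held 101 times the summed CPM of the highest APC-WT library. Different genetic backgrounds of the 2 groups might give such genes in clusters. The antigen receptor segment Igkv4-90 was left out of the test for neighbours. Of the 16 genes tested, 0 had another of a different symbol stem within 2 Mb, a condition that leaves out the clustered Serpina1 copies. Random sets of the same size had a median of 0 as well, so that test could not have counted against this explanation, which stays open.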
